A study of Arabidopsis thaliana with 6 samples.

How the data were processed

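Transcript levels had been measured in young leaves of Arabidopsis thaliana, accession Columbia-0, on 6 Affymetrix ATH1 arrays, each hybridised with total RNA from leaves 1 and 2. Per the labels, 3 arrays came from AN3-GR plants and 3 from wild type plants, described as biological repeats. AN3-GR stands for AN3 joined to the glucocorticoid receptor domain, which keeps a fused protein inactive until a steroid such as dexamethasone is given. Per the labels' protocols, seedlings grew in vitro for 8 days under 16 h of light and 8 h of darkness, and both genotypes were then moved to 5 µM dexamethasone for 8 h before the leaves were dissected in RNAlater. Untreated AN3-GR plants were not analysed here, so a lasting difference between the lines and the response to activation of the fusion are not separated.

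The deposited values were log2 expression values, and the submitters' processing notes name RMA and limma for the authors' processing, with no versions given. RMA corrects the background, makes the probe intensities of all arrays follow one distribution and summarises the probes of each set on the log2 scale. It therefore removes a shift shared by all genes, and it shrinks differences between weak signals. Per the file headers, each probe set carries the identifier of 1 Arabidopsis gene locus. This points to a gene-centred grouping of the probes, whose version is not given in the sources used here. The table held 21428 probe sets, 0 of them controls, and 0 columns of samples were left unused. Of the loci, 21231 matched the RefSeq gene table of the assembly TAIR10.1, which gave gene symbols and the order of neighbouring genes, and 197 did not match. There were 221 probe sets whose values were identical to those of another, in 106 groups, of which 47 held a locus of the mitochondrial genome. Each was tested, and 0 of the called probe sets belonged to such a group.

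The values were used as deposited, with no filter on weak signals and no further scaling. The genotypes were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with 1 prior variance for all probe sets, all 6 arrays in the fit and no covariate. The tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets. A probe set was called changed at an adjusted p under 0.05. A positive log2 change means a higher level in AN3-GR. The number of arrays, 3 per group, limits the precision of every value.

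The design, the first set of other settings, the rule for naming genes and 34 gene lists were fixed before the data were examined. Genes were named when they were among the 12 largest rises or the 12 largest falls with an adjusted p under 0.05 and all arrays of a group on the same side of the other group. Members of the lists past that threshold were named too, and AN3, the growth-regulating factors and the other loci named as AN3 targets by the study were named in every case. The list of target loci was recalled from the published study, and its members were not checked against a source. If that study chose them with these arrays, fixing the list beforehand does not make its test independent. The lists held 425 entries and 417 distinct loci, of which 383 were measured, so a few loci stand in more than 1 list. Each list was tested with camera in limma at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 34 lists. This test asks whether the mean of the members' t-statistics is higher or lower than that of other genes, so a single extreme member can move it. Counts of members past the threshold are given over all probe sets and adjusted over the list alone. Members named because they passed only adjusted over the list alone, or only with the replicate block, were chosen after their values were seen.

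The labels number the repeats 1 to 3 in both genotypes, and no label says that a number marks a shared day. Whether the numbers pair the arrays was checked from the correlation of each array's deviations from its group mean with those of the array of the same number. It was 0.161 for replicate 1, 0.416 for replicate 2 and 0.494 for replicate 3. Each lay above a bound of 0.1, which was set after these values, or values close to them, had been seen. The mean over these pairs, 0.357, was the highest of the 6 ways to match the numbers, and the next was 0.190. A rank among only 6 matchings is weak evidence. The pairing thus rests on the numbers in the labels, and the data do not settle it. The fit with the replicate number as a block was among the settings fixed in advance, and its values stand beside the results whose call or count it changes.

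The other settings fixed in advance were another quantile normalization, centring each array on its median, leaving out the 25% or 50% of probe sets with the lowest mean, an intensity trend with robust prior variance, array weights, the replicate block, leaving out each array in turn, a minimum change of 1.5-fold and Benjamini-Yekutieli adjustment. For the lists they also included camera with an estimated correlation and fry. Leaving out both arrays of a replicate number, keeping identical probe sets once, and a random block on the replicate number (statmod 1.5.0) were added after seeing the data. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

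The comparison of AN3-GR with wild type was tested on simulated data with 21428 probe sets and 50 genes changed at each size. The limma fit recovered 20% of genes changed by 0.5 on the log2 scale, 88% of those changed by 1, and 100% of those changed by 2 or 3, and it called 4 unchanged genes. With the replicate block, and no pairing in the simulation, it recovered 0% at 0.5 and 60% at 1. A simulated list of independent genes shifted by 0.25 had an adjusted p of 1.96e-05 from camera with the preset correlation. With an estimated correlation its adjusted p was 0.202, so that setting missed a real shift of this size with this number of arrays. Correlated genes were not simulated, while the estimated correlation of the photosystem list was 0.834. Whether the preset correlation gives false calls for such lists was therefore not tested.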

Results

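Transcript levels in the first pair of developing leaves were compared between AN3-GR and wild type seedlings, all treated with 5 µM dexamethasone for 8 h. AN3, also known as GIF1, is a transcriptional coactivator that binds growth-regulating factors and SWI/SNF chromatin remodelling complexes and promotes cell proliferation in leaves. The comparison asks which transcripts differ between the genotypes after dexamethasone, which activates the AN3 fusion. The growth stage of the leaves was not measured here. There were 3 arrays per genotype with 21428 probe sets each, and array medians lay between 6.22 and 6.32 on the log2 scale. Lower quartiles were 4.21 and 4.13 on wild type replicates 1 and 2, against 3.99 to 4.05 on the other arrays. Small falls of weak probe sets in AN3-GR are to be read with this difference in mind. Across genes, Pearson's r was 0.993 to 0.997 between arrays of one genotype and 0.990 to 0.995 between genotypes. Wild type replicate 3 had a higher r with AN3-GR replicate 3 (0.995) than with wild type replicate 1 (0.993) or 2 (0.994).

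AN3 itself was 8.26-fold higher in AN3-GR leaves. Its expression value was 10.37 ± 0.31 in AN3-GR and 7.33 ± 0.32 in wild type (log2, SD, n = 3 each). The log2 change was 3.05 (SE 0.19; limma with Benjamini-Hochberg adjustment, adjusted p = 0.000303), and each AN3-GR array lay above each wild type array. The probe set does not separate the transcript of the transgene from that of the native gene. Its relatives GIF2 and GIF3 had log2 changes of 0.11 (SE 0.10) and 0.04 (SE 0.18) and did not pass the test, so that 1 of the 3 family members was higher, also when adjusted over the list alone. The camera test gave this family an adjusted p of 0.0148, which rests on AN3, and adjusted p = 0.423 with an estimated correlation.

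Several growth-regulating factors, the DNA-binding partners of AN3, were higher in AN3-GR. Of the 7 measured, 4 rose, namely GRF5 by 1.22 (SE 0.13), GRF6 by 0.94 (SE 0.14), GRF3 by 0.63 (SE 0.11) and GRF8 by 0.59 (SE 0.11) on the log2 scale. Their adjusted p-values from limma with Benjamini-Hochberg adjustment were 0.0114, 0.0328, 0.0418 and 0.0485. GRF8 had a weak signal, with means of 4.84 in AN3-GR and 4.25 in wild type. GRF1 at 0.30 (SE 0.12), GRF2 at 0.18 (SE 0.12) and GRF7 at −0.12 (SE 0.22) did not pass, and GRF4 and GRF9 were not analysed here. In total 5 passed, GRF1 included, adjusted over the list alone. The list had a median change of 0.59 and a higher mean t-statistic than other genes (camera in limma, Benjamini-Hochberg adjusted p = 1.28e-05, and adjusted p = 0.188 with an estimated correlation). None of the 4 calls held without AN3-GR replicate 1 (GRF5 adjusted p = 0.0775), wild type replicate 1 (0.0528) or wild type replicate 2 (0.0976). Without AN3-GR replicate 2 or 3, only GRF5 passed in limma (adjusted p = 0.0220 and 0.0429), and centring the arrays on their medians ended the call of GRF8 (0.0618).

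Of 7 loci recalled from the published study as named AN3 targets, a membership not checked against a source, 6 were higher in AN3-GR. Beside GRF3, GRF5 and GRF6 these were COL5, a CONSTANS-like factor, at a log2 change of 1.76 (SE 0.29), HEC1, a bHLH transcription factor, at 1.31 (SE 0.22), and the cytokinin response factor CRF2 at 0.54 (SE 0.09). Their adjusted p-values from limma were 0.0414, 0.0418 and 0.0414 after Benjamini-Hochberg adjustment. ARR4, a type-A response regulator that dampens cytokinin signalling, had a change of −0.58 (SE 0.11) and an adjusted p of 0.0523, which became 0.0244 with the replicate block in limma. There were 6 that passed as higher and 1 as lower adjusted over the list alone. How the study chose these loci was not checked here. If it used these arrays, neither the counts nor the camera and fry tests of this list are independent evidence of their direction. The list's median change was 0.94 (camera adjusted p = 5.48e-06, and adjusted p = 0.188 with an estimated correlation). With the weakest 50% of probe sets left out, which removed COL5, HEC1 and GRF6 from the list, it was 0.59 (camera adjusted p = 0.0463). Over all probe sets 0 of the 7 loci passed without AN3-GR replicate 1, wild type replicate 1 or wild type replicate 2, and 1 passed without AN3-GR replicate 2 or 3. All 7 passed without wild type replicate 3, and 5 after centring the arrays on their medians, where CRF2 had an adjusted p of 0.0550.

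**Figure D1:**
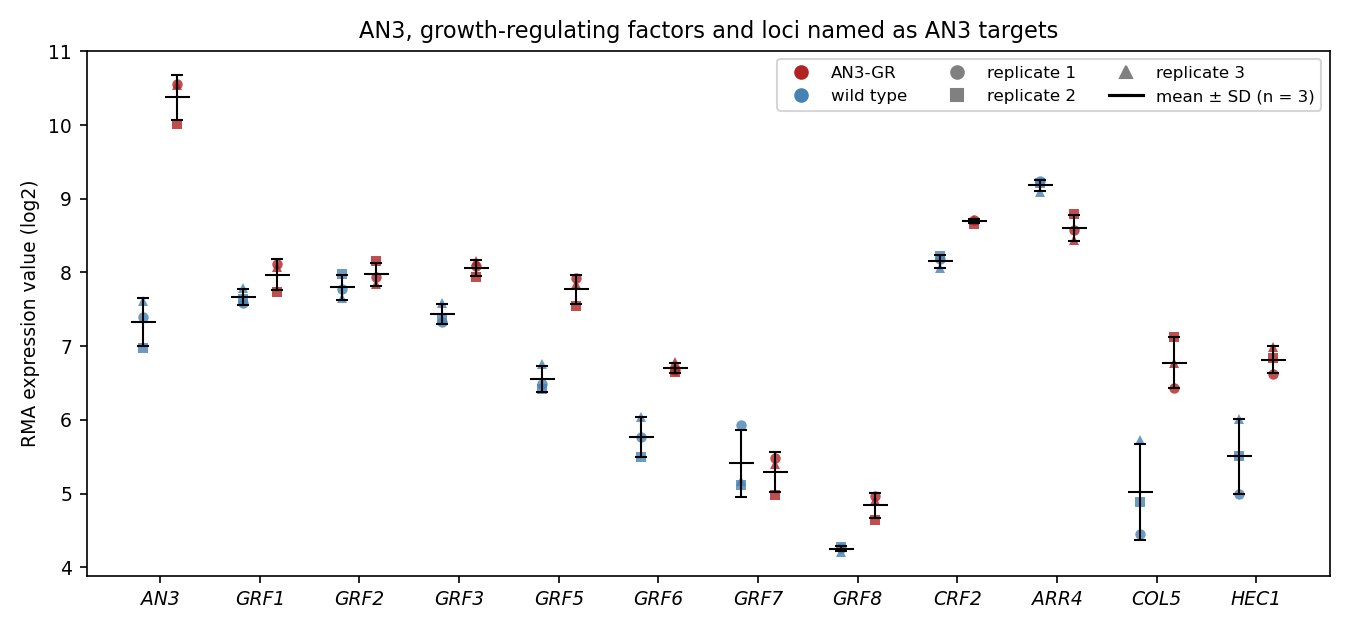
Expression values (RMA, log2) of AN3, the growth-regulating factors and the loci named as AN3 targets on each of the 3 AN3-GR arrays (red) and 3 wild type arrays (blue), with marker shapes for the replicate numbers and black bars for mean ± SD. AN3 lies near 10.37 in AN3-GR and 7.33 in wild type, GRF1, GRF2 and GRF7 overlap between the genotypes, and ARR4 is the locus that lies lower on all AN3-GR arrays.

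Cytokinin signalling genes fell into lists of opposite direction. All 5 measured cytokinin response factors had positive changes with a median of 0.41, and CRF2 passed over all probe sets. CRF1 at 0.31, CRF2 and CRF5 at 0.41 passed when adjusted over the list alone, 3 in all. The list had a higher mean t-statistic than other genes (camera in limma, adjusted p = 0.00107, and adjusted p = 0.188 with an estimated correlation). All 10 type-A response regulators had negative changes with a median of −0.31, and 0 passed over all probe sets. ARR3 and ARR17 lie under the lower quartile of all probe sets, 4.06, in both genotypes. The AN3-GR means of ARR5, 4.21, and ARR6, 4.27, lie near it, so the sizes of these changes are uncertain. Of the regulators 4 were lower adjusted over the list alone, namely ARR5 at −0.79, ARR6 at −0.70, ARR4 at −0.58 and ARR16 at −0.32, and with the replicate block 3 were lower over all probe sets, ARR4, ARR5 and ARR6. The camera adjusted p was 0.000297, and adjusted p = 0.188 with an estimated correlation. The 9 measured genes of cytokinin synthesis and breakdown had a median of −0.13 and were not called (camera adjusted p = 0.707), with 0 members past either threshold. Their median level was weak, at 4.42.

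The largest rise after AN3 was that of CDPK2, a calcium-dependent protein kinase, at 6.03-fold (log2 change 2.59, SE 0.14). APS3, an ATP sulfurylase of sulfate assimilation, rose 3.57-fold (log2 change 1.84, SE 0.14), and the locus AT3G15357 rose 3.15-fold (1.65, SE 0.14). The other rises among the 12 largest were AT5G22580 (1.80), AT1G51380 (1.30), AT5G56220 (1.29), AT5G59130 (1.18) and TOM7-2, a subunit of the mitochondrial import machinery (1.03), together with COL5, HEC1 and GRF5. The largest falls were those of AT5G24240, 5.85-fold lower in AN3-GR (log2 change −2.55, SE 0.14), and QQS, a gene linked to leaf starch, 3.91-fold lower (−1.97, SE 0.18). The AN3-GR mean of AT5G24240, 3.72, lies under the lower quartile of all probe sets, 4.06, so the size of its fold is uncertain. AT1G26190, which the gene table also names TTM2, was 3.82-fold lower (−1.93, SE 0.10). Next came the purple acid phosphatase gene PAP8 (−1.40), AT5G55450 (−1.29), AT1G60590 (−1.17), the nitrilase gene NIT4 (−1.09), MIPS1 of inositol synthesis (−1.04) and DIR1, a lipid transfer protein of systemic resistance (−1.02). AT3G16120 (−1.0), AT1G65490 (−0.99) and AT2G41090 (−0.94) completed the 12. The adjusted p-values of all these genes, from limma with Benjamini-Hochberg adjustment, lay between 0.000112 and 0.0459.

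In all, 169 probe sets changed, 120 higher and 49 lower in AN3-GR (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 134 changed by at least 1.5-fold and 23 by over 1 on the log2 scale, 13 higher and 10 lower. Without a single array the count was 10, 21 or 22 (AN3-GR replicate 1, 2 or 3), 12 or 9 (wild type replicate 1 or 2), and 779 without wild type replicate 3. Of the 169, 8 passed in all 6 of these fits, with AN3, CDPK2, APS3 and AT3G15357 higher and AT1G26190, AT5G24240, QQS and AT5G55450 lower. With the replicate block 1420 probe sets changed, 770 higher and 650 lower. These included all 169, whose signs the block cannot turn, since it leaves the log2 changes as they are. After centring the arrays on their medians 69 were higher and 70 lower, so the share of higher calls was 49.6% in place of 71.0%.

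Genes of the cell division cycle were slightly higher in AN3-GR as lists, while 0 of their members passed over all probe sets. All 17 measured genes of DNA replication had positive changes, such as ORC3 at 0.56, MCM2 at 0.46 and CDT1A at 0.41. Their median was 0.24, with 0.14 without AN3-GR replicate 3 and 0.36 without wild type replicate 3. All 17 genes of the G2/M phase and cytokinesis were positive too, with a median of 0.23, such as CYCB2;2 at 0.46 and CDKB2;1 at 0.45. ORC3 passed in the first list (1 gene) and CYCB2;2 and CDKB2;1 in the other (2 genes) when adjusted over the list alone. With the replicate block 2 and 3 members passed over all probe sets, with MCM2 and HINKEL added. The camera adjusted p-values were 3.42e-05 and 5.48e-06, and both lists had adjusted p = 0.423 with an estimated correlation. On the same arrays the touch and early stress genes, which respond to handling, had a median of −0.45.

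The D-type cyclins, which drive entry into the cycle, had a median of 0.26 over 9 genes (camera adjusted p = 0.0227, and adjusted p = 0.423 with an estimated correlation). Of these 0 passed over all probe sets, and CYCD3;3 at 0.46 passed adjusted over the list alone and, as 1 gene, with the replicate block. The 11 cell cycle inhibitors and endocycle regulators were not called (median 0.02, adjusted p = 0.741). Of these, KRP3 at 0.55 and SMR1 at −0.60 were the 2 that passed adjusted over the list alone and with the replicate block, and 0 passed without it. The 13 SWI/SNF subunits were all positive with a median of 0.15 (0.0945 without AN3-GR replicate 3), and 0 passed over all probe sets (camera adjusted p = 0.00705, and adjusted p = 0.218 with an estimated correlation). CHR23 at 0.36 passed adjusted over the list alone and, as 1 subunit, with the replicate block. The 12 other leaf growth regulators had a median of 0.23 and 0 passed over all probe sets or over the list alone (camera adjusted p = 0.0148, and adjusted p = 0.455 with an estimated correlation). NUB, at 0.50, was the 1 that passed with the replicate block. With single arrays left out, the call for D-type cyclins ended without AN3-GR replicate 3 (0.0510), wild type replicate 1 (0.0526) or wild type replicate 2 (0.0913), and with another quantile normalization (0.0724). That for the other growth regulators ended without wild type replicate 1 (0.0543) or 2 (0.0923, median 0.13), and both calls ended with the weakest 25% of probe sets left out (0.0772 and 0.0590).

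**Figure D2:**
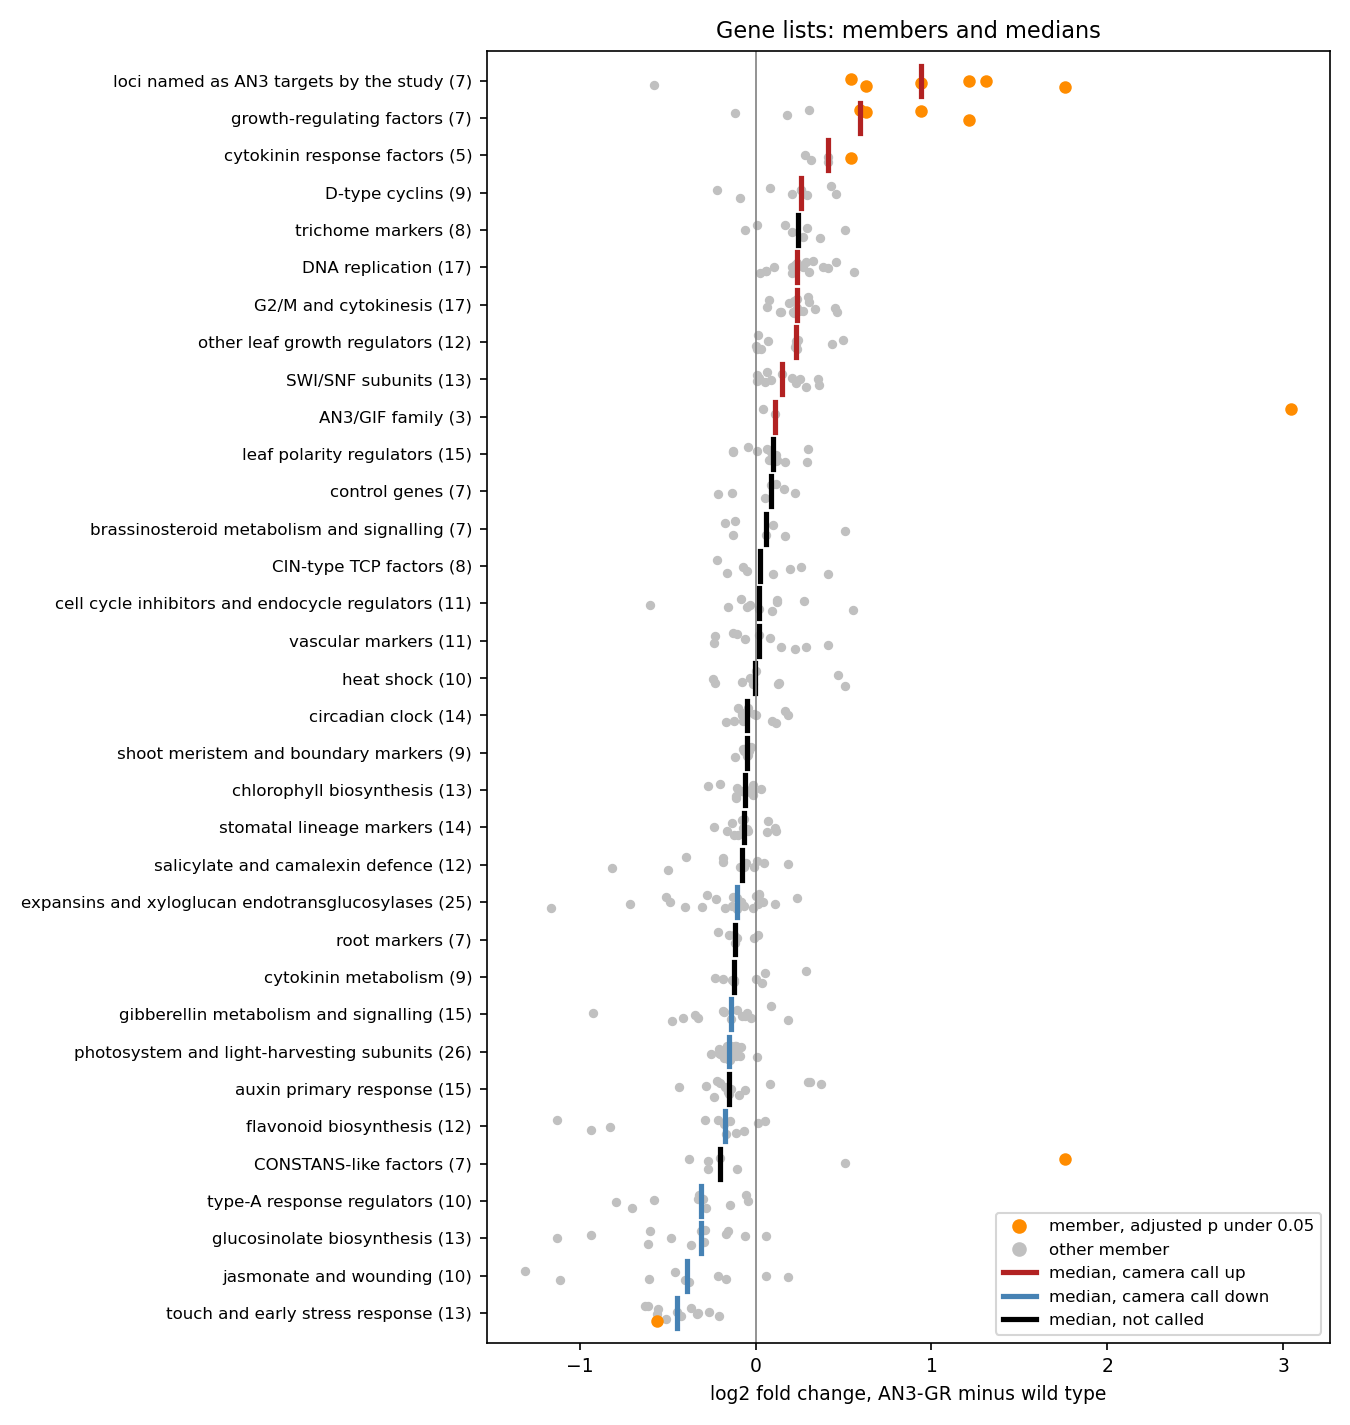
Log2 change (AN3-GR minus wild type) of each measured member of the 34 gene lists, with members past an adjusted p of 0.05 in orange, the others in grey and each list's median as a bar coloured by the camera test with the preset correlation; numbers in brackets are measured members. Medians run from −0.45 for touch and early stress genes to 0.94 for the loci named as AN3 targets.

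Stress-responsive and wound-responsive genes were lower in AN3-GR as lists. All 13 touch and early stress genes had negative changes with a median of −0.45, and ERF11, an ethylene-response factor, fell by 0.56 (SE 0.09; limma with Benjamini-Hochberg adjustment, adjusted p = 0.0407). Adjusted over the list alone 5 were lower, ERF11, WRKY40 at −0.61, CBF1 at −0.56, ERF6 at −0.45 and ZAT12 at −0.42, and with the replicate block 8 were lower over all probe sets. ERF11 passed without wild type replicate 3 (0.0355) but not without any other single array (adjusted p from 0.0769 without wild type replicate 1 to 0.232 without AN3-GR replicate 1). Of 10 jasmonate and wounding genes 8 were negative, with a median of −0.39, and 0 passed over all probe sets. Adjusted over the list alone 6 were lower, among them the jasmonate signalling repressor JAZ1 at −1.31 (SE 0.25) and the lipoxygenase LOX2 at −1.11 (SE 0.41), and 5 with the replicate block. The camera adjusted p-values were 5.48e-06 and 0.000919, with adjusted p = 0.423 and adjusted p = 0.380 with an estimated correlation. The 12 salicylate and camalexin genes (median −0.08) were not called (adjusted p = 0.0717), except without wild type replicate 1 (0.0212) or both arrays of replicate 1 (0.0148), and 0 members passed. WRKY70 was the 1 that passed with the replicate block. The 10 heat shock genes were not called either (0.655), with a median of −0.01, a mean of 0.06 and a test direction of up. HSP90.1 was the 1 heat shock gene that passed adjusted over the list alone and with the replicate block, and 0 passed without it.

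Lists of metabolism and cell wall genes were lower as well. Of 13 glucosinolate genes 12 were negative with a median of −0.31, and 0 passed over all probe sets (camera adjusted p = 0.000582, and adjusted p = 0.423 with an estimated correlation). Adjusted over the list alone MAM1 at −1.13, CYP83A1 at −0.93 and BCAT4 at −0.61, all of the methionine-derived branch, were lower (3 genes), and with the replicate block 5 were. Of 26 photosystem and light-harvesting genes 25 were negative with a median of −0.15, and 0 passed in any of these ways (camera adjusted p = 0.000582, and adjusted p = 0.624 with an estimated correlation). The 25 expansins and xyloglucan endotransglucosylases, which loosen cell walls, had a median of −0.11 (camera adjusted p = 0.0107, and adjusted p = 0.423 with an estimated correlation). Of these 0 passed over all probe sets, while EXPA8 at −1.16, XTH18 at −0.71, EXPA10 at −0.49 and XTH17 at −0.40 passed adjusted over the list alone. With the replicate block 4 passed, with XTH22 in place of XTH17. The means of XTH17, 3.51 in AN3-GR and 3.91 in wild type, lie under the lower quartile of all probe sets, 4.06. The 12 flavonoid genes had a median of −0.17 (camera adjusted p = 0.0119, and adjusted p = 0.545 with an estimated correlation). Of the flavonoid genes 0 passed adjusted over the list alone, and with the replicate block 3 were lower, DFR at −1.13, PAP2 at −0.94 and PAP1 at −0.83. The 15 gibberellin genes had a median of −0.14 (camera adjusted p = 0.0264, and adjusted p = 0.380 with an estimated correlation). Of the gibberellin genes 0 passed adjusted over the list alone, and with the replicate block 2 were lower, GA2OX2 at −0.47 and GA2OX6 at −0.41. With single arrays left out, the expansin call ended without wild type replicate 3 (0.263), where the median was −0.0194, the flavonoid call without AN3-GR replicate 3 (0.107, median −0.10) or wild type replicate 1 (0.130, median −0.11), and the gibberellin call without AN3-GR replicate 1 (0.0763) or wild type replicate 3 (0.130).

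**Figure D3:**
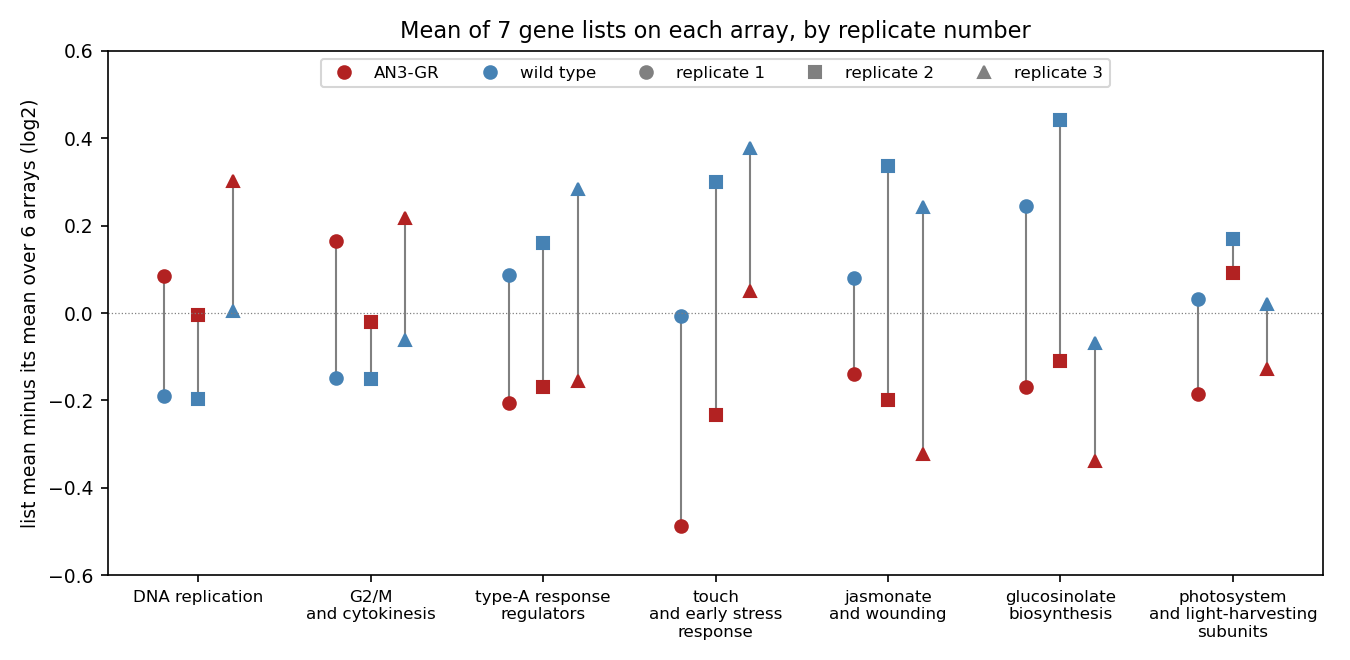
Mean expression of 7 gene lists on each array, as the difference from the list's mean over all 6 arrays (log2), with AN3-GR in red, wild type in blue, marker shapes for replicate numbers and grey lines joining arrays of the same number. In each of the 3 pairs AN3-GR lies above wild type for the DNA replication and G2/M lists and below it for the other lists plotted.

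Markers of other tissues and cell types were not called between the genotypes. The meristem and root markers were weak, with median levels of 3.61 and 4.41 against a lower quartile of all probe sets of 4.06. For these the lack of a call says little about tissue content. Camera gave adjusted p-values of 0.507 for the 9 shoot meristem and boundary markers (median −0.05), 0.297 for the 7 root markers (−0.12), 0.469 for the 14 stomatal lineage markers (−0.07) and 0.655 for the 11 vascular markers (0.02). The 8 trichome markers had a median of 0.24 (adjusted p = 0.114) and passed without wild type replicate 3 (0.00125, median 0.37), without both arrays of replicate 3 (0.000593, median 0.34) and with array weights (0.0194, median 0.32), while the median was 0.01 without both arrays of replicate 1 (0.893). The leaf polarity regulators (15 genes, median 0.10, adjusted p = 0.175), the CIN-type TCP factors (8 genes, 0.02, 0.398), the chlorophyll biosynthesis genes (13 genes, −0.06, 0.20) and the circadian clock genes (14 genes, −0.05, 0.707) were not called. Neither were the auxin response genes (15 genes, −0.15, 0.297), the brassinosteroid genes (7 genes, 0.06, 0.655) or the 7 control genes (0.09, 0.552). In these lists 0 members passed over all probe sets or adjusted over the list alone, and TCP2 was the 1 that passed with the replicate block. The 7 CONSTANS-like factors had a median of −0.20, a mean of 0.15, because COL5 was higher, and a camera direction of down (adjusted p = 0.655). Adjusted over the list alone 4 of them passed, COL5 and CO as higher and COL1 and COL4 as lower, against COL5 alone over all probe sets and COL5 and CO with the replicate block. The 26 mitochondrial-genome probe sets with values of their own had array medians of 4.02, 3.91 and 3.90 in AN3-GR and 4.14, 4.1 and 3.81 in wild type, and 0 of them changed.

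Of the 34 lists, 17 passed the camera test with the preset correlation, 9 higher and 8 lower, and 17 did with the replicate block. With an estimated correlation 0 passed, and the smallest adjusted p was 0.188 in limma. The self-contained test fry in limma called 6 after Benjamini-Hochberg adjustment, the AN3/GIF family, the growth-regulating factors, the loci named as AN3 targets, the SWI/SNF subunits, the type-A response regulators and the cytokinin response factors. These are not 6 separate results. GRF3, GRF5, GRF6, CRF2 and ARR4 stand both in the target list and in another of these lists. The target loci may also have been chosen with these arrays, which was not checked. In the AN3/GIF family only AN3, the gene of the transgene, passed in limma.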

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

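Leaving out both arrays of a replicate number, keeping identical probe sets once and the random replicate block were chosen after the data were seen. AN3 stayed called in each setting in which its value was refitted, with log2 changes of 2.87 to 3.23 when arrays were left out, and no call among the 169 turned its sign in any refit that tested it (122 were tested with the weakest 50% left out). With arrays left out, blocked or weighted no sign could turn, because for all 169 the arrays did not overlap between the genotypes. Another quantile normalization gave 241 changed probe sets (140 higher, 101 lower), centring the arrays on their medians 139 (69 and 70) and leaving out the weakest 25% of probe sets 242 (168 and 74). Leaving out the weakest 50% gave 564 (392 and 172) with 10714 tested, and the trend with robust prior variance 558 (380 and 178). Array weights gave 1132 (730 and 402), with weights from 0.514 for wild type replicate 3 to 2.28 for AN3-GR replicate 1. The replicate block gave 1420 (770 and 650) and the random replicate block 1860 (1123 and 737; consensus correlation 0.353). Benjamini-Yekutieli adjustment left 8 (4 and 4), a minimum of 1.5-fold 134, and identical probe sets kept once 197 (135 and 62). With arrays left out the total ranged from 4 to 779, the higher calls from 2 to 468 and the lower from 2 to 311; fewer arrays leave fewer degrees of freedom, but the rise to 779 without wild type replicate 3 is not of that kind. Apart from the filters, which test fewer probe sets, the cause of these moves was not tested.

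The 28 called genes that are named kept their call in 185 of 187 values from all 6 arrays and in 106 of 252 with arrays left out, and 0 reversed. As their arrays did not overlap between the genotypes, no reversal was possible with arrays left out. Of the 17 called lists 12 held with every array or pair of arrays left out and 13 in every full-data setting with the preset correlation, 11 in both; an estimated correlation left 0 and fry 6. SWI/SNF subunits lost the call with the weakest 50% left out (adjusted p = 0.0631), and flavonoid genes with array weights (0.0957). With the weakest 50% left out the chlorophyll (0.0463) and CONSTANS-like (0.0224) lists were called as lower. That filter removed COL5, the called rise of the CONSTANS-like list. Beyond the values in the report, the replicate block changed no call. Test directions that reversed belong to items that were not called. They were cytokinin metabolism (median −0.0429, test direction up), cell cycle inhibitors (0.0177, test direction down) and meristem markers (0.0297) with another quantile normalization, and cell cycle inhibitors again with the weakest 25% (0.0203, test direction down) or 50% (−0.0422) left out. With the weakest 50% left out the auxin (0.0797), brassinosteroid (−0.0270) and vascular (−0.0834) lists reversed too. With arrays left out, GRF7 reversed (−0.29 to 0.14), as did the test directions of heat shock (medians −0.00654 to 0.0897), vascular (−0.0491 to 0.0817), cell cycle inhibitors (−0.0387 to 0.0911), circadian (−0.11 to 0.0452), cytokinin metabolism (−0.22 to 0.0966) and CONSTANS-like genes (−0.26 to −0.14). Medians alone crossed 0 with arrays left out for brassinosteroid (−0.0103 to 0.0654), TCP (−0.0326 to 0.115) and meristem (−0.0931 to 0.0205) genes, and some medians near 0 did so in full-data settings. The cause was not tested. Each locus has 1 probe set, so a test per gene and the mean over a gene's probe sets were not run. Weak signals are compressed by RMA, and detection calls were not used here, so small changes in weak probe sets may be understated.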

Other observations

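The tests on a shared batch, on a wrong label of wild type replicate 3 and on shoot meristem were chosen after their results, or values close to them, had been seen, and so were the weight given to the estimated correlations in the replicate-pair test and the reading of all called genes for a share of AN3-GR RNA.

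Of 33 measured genes of ribosome biogenesis, which build ribosomal subunits in the nucleolus, 6 were higher in AN3-GR. The list of 34 genes was written after the largest calls had been seen, and 3 of them, EBP2, TOZ and SWA1, were known to be higher by then. All 33 had positive changes with a median of 0.45. Without the 3 seen members, all 30 were positive with a median of 0.42, and 3 passed over all probe sets in limma, NSN1 at 0.64, CBF5 at 0.63 and BOP1 at 0.59. With the replicate block 25 passed. Camera gave the list of 30 p = 8.74e-24 with the preset correlation and p = 0.0328 with an estimated correlation, and fry gave p = 0.00201. These p-values are unadjusted, so they cannot be set beside the adjusted values of the lists fixed in advance. With an estimated correlation p was above 0.05 without AN3-GR replicate 3 (0.0675), wild type replicate 2 (0.0663) or wild type replicate 3 (0.0953), and after median centring (0.0508). A candidate hypothesis is that ribosome biogenesis is raised as a group in AN3-GR leaves, but the theme was found and tested on the same arrays.

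The real grouping of the 6 arrays gave 169 changed probe sets in limma, and the highest count among the other splits into 3 and 3 was 0. Thus 1 of the 10 splits reached the real count, which is too few splits for a share under 0.05. With the replicate block the real split gave 1420, and the 3 other splits that part every pair gave 0. The other splits mix the genotypes, so any difference between these adds to the spread within groups and lowers their counts.

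Calls rose to 779 without wild type replicate 3 and to 1420 with the replicate block. A wrong label is argued against, since this array's AN3 value of 7.61 lies 2.41 below the lowest AN3-GR array, 7.75 times the SD of the AN3-GR arrays, against a bound set after the value was seen. A share of AN3-GR RNA in this array was judged by its excess of AN3 over the other wild type arrays. That excess is 4.02% of the AN3-GR excess, under the bound of 10% set beforehand. Its spread of 3.02% rests on only those other wild type arrays, too few to decide, so a share below or above 10% stays open. Such a share would move all called genes alike. The median is 8.96% over the 119 other rises (59 at 10% or more, such as COL5 at 31.6%, against 1.64% for CDPK2 and −12.1% for APS3) and −3.52% over the 49 falls (17 at 10% or more). These genes were called with this array in the fit, so genes that it moved towards AN3-GR tended to drop out. Their shares therefore cannot decide the question. A day or batch shared by arrays of one number may account for part of the spread, since the mean correlation of deviations within numbers is 0.357, the highest of the 6 matchings. A rank among 6 is weak evidence, no label gives a day, and a difference between the plants used for each repeat stays open.

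Single genes changed by over 1 on the log2 scale, AN3 left out, were 22 in number and lay on all 5 chromosomes. One stretch of chromosome that differs between the lines is argued against, since the fullest window of 200 neighbouring measured loci held 3 of them, or 13.6%. Clusters of neighbours at several places are argued against as well, since 0 of them had another within the 20 nearest measured loci, where the 95th percentile of 10000 random sets was 4. Differences between the lines at single scattered genes, such as AT5G24240, AT1G26190 or QQS, could still account for part of the pattern and were not tested, because no AN3-GR plants without dexamethasone were analysed here. A response to the activated fusion stays open on the same ground.

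Cell cycle lists were higher while stress, jasmonate and photosystem lists were lower in AN3-GR. If stage or handling had differed only between single arrays, signs should vary between replicate pairs, yet 5 of the 5 lists kept a single sign in all 3 pairs, with a mean beyond the SD of the pair differences. That bound was set beforehand and met, but 3 pairs agree in sign easily and the members move together (estimated correlations 0.183 to 0.834, adjusted p 0.380 to 0.624 with them), so array differences and genotype cannot be told apart here. More shoot meristem in the AN3-GR samples is not borne out by its markers, whose median change was −0.0476, but their median level of 3.61 lies under the lower quartile of 4.06 and 3 of 9 lie above it, so a small share could go unseen. An effect of AN3 on proliferation stays open with a difference in stage between the genotypes.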
